A study of Mus musculus with 9 samples.

How the data were processed

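RNA sequencing libraries were made from 9 samples of mouse CD8+ T cells that carried a short hairpin RNA and had been sorted by CD4 (read length 50 bases, paired ends, per the labels' protocols). The deposited table held expected counts: estimated counts per gene and library, not scaled, with 40.9% of the values whole numbers (tolerance 0). Kallisto and limma are named in the submitters' processing notes, with genome build mm10 and no versions, and the roles of these tools and any filter on genes are not given in the sources used here. The table had 22842 entries, of which 92 were external RNA controls (ERCC spike-ins) and 22750 were genes. Symbols, positions and transcript sequences were taken from GENCODE M21 (GRCm38, the same assembly as mm10), and 376 genes had no symbol there. Of the genes tested, 228 had no symbol and stayed in every test.

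The libraries formed 5 groups by the gene targeted and the CD4 sort: 4 knock-down groups of 2 libraries each and 1 control library. In each knock-down group the libraries carried different hairpins, and a CD4-positive and a CD4-negative library shared each hairpin number. On that ground an alternative model with the hairpin as a block was chosen before the data were examined. In the data, the deviations of libraries from their group mean correlated between the CD4-negative and CD4-positive libraries of a hairpin (0.23 across genes for Chaf1a and 0.13 for Dnmt1). The consensus correlation of libraries of a hairpin, estimated in limma, was 0.379.

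Counts were rounded to whole numbers. Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 17002. Libraries were scaled by the trimmed mean of M values. A quasi-likelihood model with a mean per group was fitted in edgeR 4.0.16 (R 4.3.3) to all 9 libraries, so that the groups shared an estimate of the spread with 4 residual degrees of freedom, a common dispersion of 0.0229 and a prior of 8.5 degrees of freedom. The single control library was assumed to vary like the other groups. Each of 8 contrasts was tested with a two-sided quasi-likelihood F test, Benjamini-Hochberg adjustment over the 17002 genes, and a threshold of 0.05 on the adjusted p. The contrasts were CD4-positive against CD4-negative cells over both knock-downs and within each, the difference between these effects, Chaf1a against Dnmt1 knock-down in each CD4 sort, and each knock-down against the control. Levels are CPM (counts over the scaled library size), with the standard deviation (SD) between libraries. Fold changes are log2 with their standard error (SE). A fold against a group at 0 is given as a lower bound, computed against 3 counts over the group. A fold against a group with 1 to 3 counts is a ratio of counts with its exact 95% Poisson interval.

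There were 26 gene lists, tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The lists covered CAF-1 and histone deposition, DNA methylation machinery, heterochromatin and H3K9 silencing, the CD4 helper lineage, the cytotoxic lineage and effectors, NK and innate-like receptors, naive and memory genes, activation and inhibitory receptors, chemokine receptors and integrins, interferon-stimulated genes, germline genes under DNA methylation, imprinted genes, 2-cell embryo genes, DNA replication and S phase, mitosis, replication-dependent histones, p53 targets, cholesterol synthesis, glycolysis and hypoxia, stress and immediate early genes, MHC class II, B cell markers, myeloid and dendritic markers, gamma-delta and NKT markers, erythroid and platelet markers, and mitochondrially encoded genes. Camera with an estimated correlation and fry were run beside it. No list test passed with an estimated correlation in any of the 8 comparisons. The correlation was there estimated with 4 residual degrees of freedom, and the power of that setting was not simulated. Failing it therefore does not show that a list is unchanged. Medians of lists hold genes at 0 on one side at the bound that 3 counts allow. Overlaps of called genes were tested with Fisher's exact test. For the control comparisons, which share the Renilla library, the covariance of fold changes was set beside that of 20 simulated pairs of unchanged groups against the same control.

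The comparisons, the lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where said. The rule named Cd4, Chaf1a and Dnmt1 in every comparison. It named the 8 called genes with the largest change in each direction among those with a mean of at least 1 CPM, no overlap between the libraries compared and a symbol that is not a clone name. It also named up to 3 members of each list with a call, the genes of smallest p up to 10 where few passed, and core lineage genes in the first comparison. From these the text takes 92 genes. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma voom, limma with correlated hairpins, no filter, a filter at a mean of 5 CPM, only the groups compared, the hairpin block, and leaving out each library in turn. The following were chosen after seeing the data: scaling by ERCC reads, a correction for GC content and length of transcripts (natural splines of both per library, known for 98.6% of tested genes), the hairpin block with that correction, thinning to equal depth, and camera on values corrected for GC content and length. The labels do not say how much spike-in was added per cell, so values with ERCC scaling may not be amounts per cell. Sharing of sequence between genes was measured as the percent of 31-base words of a gene's transcripts that occur in transcripts of another gene.

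The gene tests, and camera with the preset correlation, were tried on simulated data drawn from these libraries' means and sizes. There 200 of 17002 genes were changed by 1.5-, 2-, 4- or 8-fold, with no difference between hairpins and each gene drawn independently. For CD4-positive against CD4-negative cells over both knock-downs the edgeR test recovered 76% of 1.5-fold and 86% of 2-fold changes and all larger ones, with 16 false calls among 197. Within Chaf1a it recovered 52% and within Dnmt1 70% of 2-fold changes, with 13 of 147 and 9 of 157 calls false. For the difference between the effects it recovered 36% of 2-fold and 84% of 4-fold changes, with 8 of 116 false. For Chaf1a against Dnmt1 it recovered 52% of 2-fold changes in CD4-negative cells (13 of 149 calls false) and 76% in CD4-positive cells (12 of 159). Against the control it recovered 62% under Chaf1a (10 of 139) and 64% under Dnmt1 (8 of 138). False calls were above 5% of calls in each of the 8 simulated comparisons. Planted lists passed camera in 8 of 8 comparisons and unchanged lists in 0, at an unadjusted p under 0.05 on voom values. The simulated genes had no correlation with each other, so this cannot show how far the list calls hold where genes are correlated. Camera with an estimated correlation and fry were not simulated.

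Gene counts summed to 24093879 to 31583882 per library. In the shallowest library a gene at 10 CPM rested on 241 counts, a counting error of 6.44%, and a gene at 1 CPM on 24 counts, an error of 20.4%. A count of 0 allowed 0.095 to 0.125 CPM, at 3 counts per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No library and no gene that passed the filter was left out of the main model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.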

Results

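Cytotoxic T cells keep Cd4, the co-receptor gene of helper T cells, switched off. The series asked what CAF-1, the histone chaperone that deposits nucleosomes behind the replication fork and whose large subunit is Chaf1a, and the maintenance DNA methyltransferase Dnmt1 contribute to that silence. Gene expression was measured by RNA sequencing in CD8+ T cells that had been activated for 24 h, infected with a retrovirus carrying a short hairpin RNA, grown for 5 days in 100 U/mL IL-2 and sorted by CD8 and CD4. Hairpins sh576 and sh3118 targeted Chaf1a, and sh1137 and sh4462 targeted Dnmt1. Each of these 4 hairpins gave a library of CD4-negative cells and a library of CD4-positive cells, that is 2 libraries in each of 4 groups. Hairpin 713, against Renilla luciferase, gave 1 CD4-negative control library, and no control library of CD4-positive cells was available. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so each p-value measures only the spread between these libraries. Gene counts summed to 28815825 and 30512392 in the Chaf1a CD4-negative libraries (sh576 and sh3118), 24093879 and 28584276 in the Chaf1a CD4-positive ones, 31583882 and 30258680 in the Dnmt1 CD4-negative ones (sh1137 and sh4462), 24316775 and 24857177 in the Dnmt1 CD4-positive ones, and 29981211 in the control.

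Each hairpin lowered its target. Chaf1a mRNA (ENSMUSG00000002835, chromosome 17, 56040439 to 56072289, mm10) stood at 47.6% and 36.1% of the Renilla library in the CD4-negative cells with hairpins sh576 and sh3118, and at 29.8% and 32.5% in the CD4-positive cells. Dnmt1 mRNA (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888) stood at 27.9% and 21.1% in the CD4-negative cells with hairpins sh1137 and sh4462, and at 19.5% and 18.9% in the CD4-positive cells. Dnmt1 stood at 96.6% to 142% of Renilla under the Chaf1a hairpins, and Chaf1a at 89.7% to 131% under the Dnmt1 hairpins. Because 51% of the 31-base words in Chaf1a transcripts also occur in transcripts annotated to the neighbouring gene Ubxn6, the size of the Chaf1a knock-down is uncertain. The sort was visible in Cd4 mRNA (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221). It averaged 1.86 ± 0.0184 CPM (SD, n = 2) in CD4-negative and 20.8 ± 2.43 (n = 2) in CD4-positive cells under Chaf1a knock-down, 1.12 ± 0.0477 (n = 2) and 53.3 ± 7.62 (n = 2) under Dnmt1 knock-down, and 1.18 CPM in the Renilla library. The first principal component, with 51.1% of the variance, set the Chaf1a libraries apart from the Dnmt1 and Renilla libraries. On the second, with 17.7%, the CD4-negative library of hairpin sh3118 and the Renilla library lay at the low end (-57.0 and -41.7). The CD4-positive library of each hairpin lay above its CD4-negative library there. On the third, with 9.99%, the Renilla library lay apart at -63.8, with the others between -9.1 and 28.6.

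**Figure D1:**
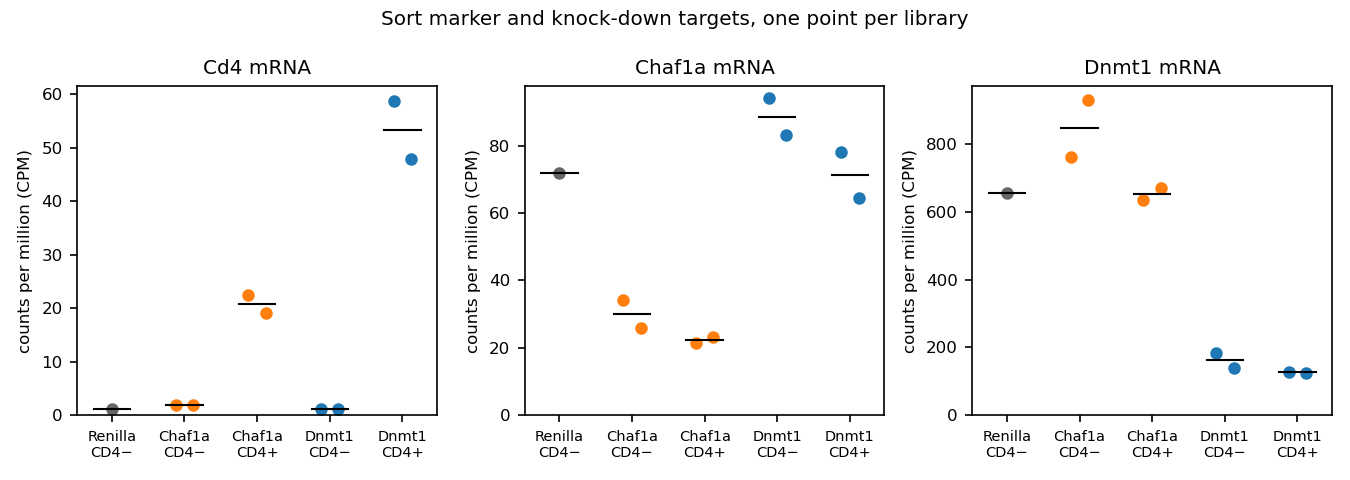
Expression (CPM) of Cd4, Chaf1a and Dnmt1 mRNA, with 1 point per library and a line at each group mean, and each axis starting at 0. Cd4 is high in the CD4-positive libraries, Chaf1a is lower than in the Renilla library in the 4 libraries with Chaf1a hairpins, and Dnmt1 is lower in the 4 with Dnmt1 hairpins.

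The comparison of CD4-positive with CD4-negative cells asked what else differs in cytotoxic T cells that have lost Cd4 silencing. Apart from Cd4 itself, which was 23.0-fold higher, the CD4-positive cells had less mRNA for several groups of genes, relative to the typical gene. These were many cytotoxic effectors and their regulators, replication-dependent histones and glycolytic enzymes, and some genes of cholesterol synthesis. With ERCC scaling the medians of these 4 lists shrank to -0.16, -0.28, -0.21 and -0.01, and none of the lists passed with an estimated correlation. Eomes, the T-box factor of effector and memory CD8 cells (chromosome 9, 118478212 to 118486132), fell from 178 ± 73.5 CPM (n = 4) to 85.1 ± 46.7 (n = 4). Gzmk, a granzyme, fell from 114 ± 110 (n = 4) to 67.2 ± 68.7 (n = 4). Mitochondrially encoded mRNAs and a few genes such as Tulp1 and Zfp229 were higher. Cd8a, Cd8b1 and Runx3, which mark the CD8 lineage, did not pass the test, with log2 changes of -0.09, -0.16 and 0.00 (0.20 and 0.12 for Cd8a and Cd8b1 with ERCC scaling).

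In all, 3529 of 17002 genes passed, 1351 higher and 2178 lower in CD4-positive cells (38.3% higher). Cd4, whose direction the sort fixed, rose by 4.52 ± 0.14 on the log2 scale (SE; adjusted p = 3.12e-09), in 4 of 4 hairpins. Among 31 cytotoxic genes 16 were lower and 1 higher (19 and 1 adjusted over the list alone), with a median of -0.46 and camera adjusted p = 3.33e-07 (adjusted p = 0.433 with an estimated correlation). They included Gzmd, another granzyme (-2.64 ± 0.38, adjusted p = 0.00532), the cytokine Ifng (-1.34), Eomes (-1.14 ± 0.11, adjusted p = 0.00102) and Gzmk (-0.92). Each of these 4 fell in 4 of 4 hairpins. The NK receptor gene Klrb1c (-1.58), the exhaustion-associated receptor Havcr2 (-0.70), the co-stimulatory receptor Tnfrsf9 (-0.50), Samd3 (-1.45) and the transcriptional repressor Zbtb32 (-1.03) were also lower. Of 22 activation and inhibitory receptors 11 were lower and 1 higher (11 and 1 adjusted over the list alone; median -0.20, camera adjusted p = 0.0299, adjusted p = 0.458 with an estimated correlation), a median that turned to 0.08 with ERCC scaling. Within Dnmt1 knock-down alone this list did not pass (median -0.19, 1 higher and 3 lower, 2 and 6 adjusted over the list alone, camera adjusted p = 0.104). Its summed level rose there from 4050 to 4670 CPM (sh1137) and from 4160 to 4570 CPM (sh4462). Zbtb7b (-0.29 ± 0.10, adjusted p = 0.0535), which encodes the helper lineage factor ThPOK, did not pass, but did with the hairpin as a block (adjusted p = 0.0141). None of 17 CD4 helper genes passed, over all genes or adjusted over the list alone, and their median of 0.29 had camera adjusted p = 0.18.

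Over both knock-downs, lists of cell growth and division had lower medians. Of 44 replication-dependent histone genes 26 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 8.71e-11; adjusted p = 0.458 with an estimated correlation). Hist1h1d (-0.92), Hist2h2ac (-0.81) and Hist1h2bb (-0.70) were examples, the last 2 sharing 64.1% and 47.7% of their sequence words with other genes. In glycolysis 15 of 21 genes fell (15 adjusted over the list alone; median -0.51, camera adjusted p = 3.57e-06, adjusted p = 0.458 with an estimated correlation), among them the enzymes Aldoa (-0.74) and Pgk1 (-0.62) and the lactate exporter Slc16a3 (-0.73). In cholesterol synthesis 9 of 20 genes fell (12 adjusted over the list alone; median -0.30, camera adjusted p = 5.4e-05, adjusted p = 0.458 with an estimated correlation), with the reductase Dhcr7 (-0.51) and the regulator Srebf2 (-0.52). In DNA replication 11 of 36 fell (14 adjusted over the list alone; median -0.23, camera adjusted p = 0.000137, adjusted p = 0.505 with an estimated correlation), with the helicase subunits Mcm5 (-0.51) and Mcm3 (-0.49). In mitosis 10 of 28 fell and 1 rose (10 and 3 adjusted over the list alone; median -0.16, camera adjusted p = 0.0143, adjusted p = 0.567 with an estimated correlation), with the kinase Plk1 (-0.65). Within Dnmt1 knock-down alone the mitosis list did not pass (median -0.11, camera adjusted p = 0.24, 0 called, 2 higher and 2 lower adjusted over the list alone), but did with a GC and length correction (adjusted p = 0.00530). Its summed level rose from 9250 to 9910 CPM (sh1137) and from 9320 to 10100 CPM (sh4462). In CAF-1 and histone deposition 4 of 14 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 0.00377, adjusted p = 0.458 with an estimated correlation). Chaf1a itself fell by 0.37 and Dnmt1 by 0.36, and Uhrf1, which brings Dnmt1 to replicated DNA, fell by 0.39. The second large CAF-1 subunit Chaf1b (-0.22, adjusted p = 0.0965; 0.06 with ERCC scaling) did not pass, and did with the hairpin block (adjusted p = 0.0236). With ERCC scaling the medians of replication, mitosis and CAF-1 genes turned to 0.06, 0.13 and 0.07, and those of cytotoxic, histone, glycolysis and cholesterol genes shrank to -0.16, -0.28, -0.21 and -0.01.

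Fewer groups were higher. Of 13 mitochondrially encoded mRNAs 8 rose (9 adjusted over the list alone; median 0.43, camera adjusted p = 0.00304, adjusted p = 0.458 with an estimated correlation), with mt-Nd4 (1.03), mt-Nd2 (0.79) and mt-Nd6 (0.68). The mitochondrial share of counts was higher in the CD4-positive library of each hairpin (4.95% against 3.86% for sh576, 4.13% against 3.43% for sh3118, 3.56% against 2.31% for sh1137 and 3.98% against 2.82% for sh4462). Of mt-Nd4 words 62.8% occur in nuclear copies, so its own level is uncertain. Of 33 interferon-stimulated genes 5 rose (4 adjusted over the list alone; median 0.16, camera adjusted p = 0.0238, adjusted p = 0.505 with an estimated correlation), led by the antiviral sensor Oas2 (1.60 ± 0.25, adjusted p = 0.00627). Within Chaf1a knock-down alone the list did not pass (median 0.07, camera adjusted p = 0.246). Its summed level went there from 2160 to 2170 CPM (sh576) and from 2530 to 2200 CPM (sh3118). Of 31 germline genes 2 rose (2 adjusted over the list alone; median 0.52, camera adjusted p = 0.00818, adjusted p = 0.458 with an estimated correlation), the meiotic genes Spo11 (1.12) and Stag3 (0.92), and within Chaf1a alone this list did not pass (median 0.27, camera adjusted p = 0.0628; 0.0465 with the hairpin block). Of 7 gamma-delta and NKT markers 3 rose (3 adjusted over the list alone; median 0.57, camera adjusted p = 0.00728, adjusted p = 0.458 with an estimated correlation), with Cd163l1 (1.25) and Tcrg-C4 (0.57). The lists of imprinted genes (6 of 20 higher and 3 lower, median 0.49, adjusted p = 0.0285) and B cell markers (2 of 12 higher, median 0.38, adjusted p = 0.0496) passed as well (adjusted p = 0.458 with an estimated correlation for both; 8 and 3, and 4, adjusted over the list alone). The summed level of the imprinted genes was lower in the CD4-positive library of each hairpin (842 to 759 CPM for sh576, 916 to 747 for sh3118, 799 to 703 for sh1137 and 751 to 643 for sh4462). Within Dnmt1 alone that list did not pass (adjusted p = 0.0715), but did with a GC and length correction (adjusted p = 0.0483). The B cell call was lost with the hairpin block (adjusted p = 0.0502). Within Chaf1a alone the B cell list did not pass (median 0.04, adjusted p = 0.238), and its summed level fell from 241 to 229 CPM (sh576) and from 288 to 227 CPM (sh3118). Outside the lists Zfp229 (1.88), Ica1l (1.79), Tulp1 (1.57 ± 0.16, adjusted p = 0.00102) and the integrin Itga4 (0.65) were higher. Among the lists that did not pass were DNA methylation machinery (0 higher and 4 lower of 17, camera adjusted p = 0.453), heterochromatin and H3K9 silencing (2 and 1 of 17, adjusted p = 0.778) and myeloid and dendritic markers (3 and 1 of 13, adjusted p = 0.0734). Neither did stress genes (1 and 3 of 16, adjusted p = 0.0734), p53 targets (1 and 5 of 22, adjusted p = 0.0759), 2-cell embryo genes (1 and 0 of 6, adjusted p = 0.165), or MHC class II (0 of 8, adjusted p = 0.278). The same held for erythroid and platelet markers (0 of 5, adjusted p = 0.379), chemokine receptors and integrins (3 and 8 of 20, adjusted p = 0.428), naive and memory genes (1 and 0 of 17, adjusted p = 0.744) and NK and innate-like receptors (1 and 1 of 8, adjusted p = 0.952).

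Leaving out the CD4-positive library of sh1137 or the CD4-negative library of sh4462 moved the number of genes little. It rested more on the other libraries. It was 5804 without the CD4-negative library of hairpin sh576, 334 without its CD4-positive library, 1267 and 1629 without the CD4-negative and CD4-positive libraries of sh3118, 503 without the CD4-negative library of sh1137, and 779 without the CD4-positive library of sh4462. Without the CD4-positive library of hairpin sh576 the following calls ended: Ifng (-1.22), Mcm5 (-0.49), Mcm3 (-0.47), Dhcr7 (-0.48), Srebf2 (-0.47), Uhrf1 (-0.38), Chaf1a (-0.34), Dnmt1 (-0.34), Stag3 (0.85), Cd163l1 (1.15) and Spo11 (1.20). The calls of Spo11 and Dnmt1 ended in 6 of the 8 omissions (at 0.99 to 1.25 and -0.26 to -0.38), that of Chaf1a in 5 (-0.26 to -0.40), and those of Uhrf1 and Mcm3 in 3. The last 2 ended also without the CD4-negative library of sh1137 (-0.34 and -0.41) and the CD4-positive library of sh4462 (-0.37 and -0.42). Chaf1a (-0.28) and Dnmt1 (-0.26) were not called with a filter at 5 CPM, nor with ERCC scaling (-0.10 and -0.06). The omissions used the main model, which does not pair libraries by hairpin. With the hairpin as a block, in the 8 knock-down libraries, 6282 genes passed, 42.3% of them higher. Scaling by ERCC reads moved the median of all genes by 0.284 towards the CD4-positive cells, so that changes above are relative to the typical gene. As the spike-in added per cell is not given, neither scaling is known to measure RNA per cell. That scaling left 1740 calls, 98.0% of them higher, and ended 14 of the 36 calls named here, among them Aldoa (-0.43), Pgk1 (-0.33), Plk1 (-0.35), Havcr2 (-0.41) and Mcm5 (-0.23). Among genes with a mean of at least 5 CPM, 50.9% of the calls were higher. Fold changes also followed the composition of transcripts, with a Spearman correlation of -0.38 with GC content and 0.34 with length across 10144 genes, which are not independent replicates. With the block and a correction for both, 5873 genes passed.

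Under Chaf1a knock-down alone, few genes passed between CD4-positive and CD4-negative cells in the main model, which does not pair libraries by hairpin. With the hairpin block 2786 genes passed. Cd4, the marker of the sort, was 11.2-fold higher and Pias4, a SUMO ligase, 2.13-fold higher. Eomes fell from 115 ± 8.70 CPM (n = 2) to 45.6 ± 11.5 (n = 2), and Gzmk from 18.3 ± 0.984 (n = 2) to 8.51 ± 0.862 (n = 2). They were among 5 calls (2 higher and 3 lower), with log2 changes of 3.48 ± 0.19 for Cd4 (adjusted p = 3.30e-06), 1.09 ± 0.15 for Pias4 (0.0459), -1.33 ± 0.16 for Eomes (0.0171) and -1.11 ± 0.14 for Gzmk (0.0244), each in the same direction in both hairpins. Ifng (-1.94 ± 0.36, adjusted p = 0.0866), Chaf1a (-0.43, adjusted p = 0.174) and Dnmt1 (-0.38, adjusted p = 0.192) did not pass, and passed with the hairpin block (adjusted p = 0.00291, 0.0377 and 0.0246). As a group, 31 cytotoxic genes had a median of -0.52 and camera adjusted p = 1.53e-09 (0 higher and 2 lower over all genes, 0 and 16 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). The 44 histone genes had a median of -0.67 (0 called, 24 lower adjusted over the list alone; camera adjusted p = 4.81e-11, adjusted p = 0.535 with an estimated correlation). The 13 myeloid and dendritic markers (0 called over all genes, 1 lower adjusted over the list alone) had a median of 0.52 and camera adjusted p = 0.0241 (adjusted p = 0.535 with an estimated correlation). Other lists with no member called over all genes also had lower medians. They were glycolysis (14 lower adjusted over the list alone; median -0.46, adjusted p = 1.99e-05), cholesterol synthesis (6; -0.29, adjusted p = 0.000139) and mitosis (9; -0.22, adjusted p = 0.000649). The others were replication (0 adjusted over the list alone; -0.21, adjusted p = 0.000757), activation and inhibitory receptors (6; -0.24, adjusted p = 0.0104) and CAF-1 genes (0; -0.22, adjusted p = 0.0108). Higher medians were those of gamma-delta and NKT markers (0 adjusted over the list alone; 0.42, adjusted p = 0.0252), imprinted genes (0; 0.34, adjusted p = 0.0356, with lower summed levels as given above) and mitochondrially encoded mRNAs (4 higher; 0.29, adjusted p = 0.0380, and 0.130 with a GC and length correction). Each of these 9 lists lost its call with an estimated correlation (adjusted p = 0.535 with an estimated correlation for each). With ERCC scaling the medians of cholesterol, mitosis, replication, activation and CAF-1 genes turned to 0.04, 0.11, 0.12, 0.09 and 0.11.

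The low count of 5 stood beside 3504 genes at an unadjusted p under 0.05, where the DESeq2 Wald test called 691 and limma voom 7. The Wald test gave Cd4 (3.50) no adjusted p, because its own filter left out 10548 genes, Cd4 among them. Gzmk (-1.11) did not pass with limma voom, and Pias4 (1.19) and Gzmk (-1.0) did not with a filter at 5 CPM. With the hairpin block 2786 genes passed, 30.3% of them higher. Single libraries were left out in the main model, without pairing by hairpin. The count rose there without the CD4-negative library of sh576. Without the CD4-positive library of sh576 or the CD4-negative library of sh3118 only the call of Cd4 was left. Without the CD4-positive library of sh3118, 4 genes passed, of which 2 were among the 5, and Pias4 (1.16) and Gzmk (-1.01) did not pass. Scaling by ERCC reads moved all genes by 0.32 and gave 8 calls, all higher, without Eomes (-0.99) and Gzmk (-0.79).

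Under Dnmt1 knock-down, Cd4, the marker of the sort, was 47.2-fold higher in CD4-positive than in CD4-negative cells. Khdc1a and Tjp1, which encodes a tight junction protein, were 6.18-fold and 4.09-fold lower. The granzymes Gzmd and Gzmk and Eomes were lower again, with Eomes at 125 ± 13.6 CPM (n = 2) against 241 ± 8.24 (n = 2). The inhibitory receptor Ctla4 rose from 144 ± 12.5 CPM (n = 2) to 250 ± 35.6 (n = 2) and Itgae, the integrin CD103, from 61.6 ± 2.0 (n = 2) to 121 ± 9.02 (n = 2).

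Here 243 genes passed, 106 higher and 137 lower. Cd4 rose by 5.56 ± 0.20 (adjusted p = 2.81e-08), Itgae by 0.98 ± 0.17 (0.0317), Ctla4 by 0.80 ± 0.15 (0.0358), mt-Nd4 by 1.25 ± 0.17 (0.0238) and Zfp229 by 2.10 ± 0.31 (0.0250). Khdc1a (-2.63 ± 0.25, adjusted p = 0.00110), Gzmd (-2.62 ± 0.54, adjusted p = 0.0463), Rgs16, a regulator of G-protein signalling (-2.04), Tjp1 (-2.03), Eomes (-0.95) and Gzmk (-0.73) were lower, each in both hairpins. Khdc1a shares 58.6% and Gzmd 38.2% of sequence words with other genes, mostly relatives, so their own levels are uncertain. Dnmt1 itself (-0.35, adjusted p = 0.166) did not pass, and did with the hairpin block (adjusted p = 0.0291), and Chaf1a (-0.31, adjusted p = 0.209) did not pass. Of 21 glycolysis genes 7 fell (14 adjusted over the list alone; median -0.55, camera adjusted p = 2.67e-06, adjusted p = 0.478 with an estimated correlation). Of 22 p53 targets 2 fell (6 lower and 1 higher adjusted over the list alone), with a median of -0.30 and camera adjusted p = 0.00850 (adjusted p = 0.478 with an estimated correlation). Histones (0 higher and 2 lower, 0 and 18 adjusted over the list alone; median -0.49, camera adjusted p = 2.90e-08), cytotoxic genes (0 and 3, 1 and 11 adjusted over the list alone; median -0.26, adjusted p = 0.000268) and cholesterol synthesis (0 called, 4 lower adjusted over the list alone; median -0.27, adjusted p = 0.000268) were lower as lists (adjusted p = 0.478 with an estimated correlation for each). So were replication (0 called, also adjusted over the list alone; median -0.22, adjusted p = 0.000361, adjusted p = 0.546 with an estimated correlation) and CAF-1 genes (0 called, also adjusted over the list alone; median -0.22, adjusted p = 0.00579, adjusted p = 0.480 with an estimated correlation), with medians of 0.01 and 0.02 under ERCC scaling.

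Higher as lists under Dnmt1 knock-down were mitochondrially encoded mRNAs (3 higher, 9 adjusted over the list alone; median 0.52, camera adjusted p = 0.000268), interferon-stimulated genes (2, and 3; median 0.27, adjusted p = 0.00311), germline genes (0, and 0; median 0.46, adjusted p = 0.00428) and gamma-delta and NKT markers (1, and 4; median 0.73, adjusted p = 0.00557). The 12 B cell markers (0, and 2; median 0.54, adjusted p = 0.0101, 0.0125 with the hairpin block) were higher too, and their summed level went from 571 to 780 CPM (sh1137) and from 549 to 683 CPM (sh4462). Each of these 5 lists lost its call with an estimated correlation (adjusted p = 0.478 with an estimated correlation for each).

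All libraries of this comparison mattered: the count was 6 without the CD4-negative and 31 without the CD4-positive library of sh1137, and 24 without either library of sh4462. Across these 4 omissions the calls of Rgs16 (-1.94 to -2.19), Gzmd (-2.10 to -3.03), Eomes (-0.88 to -1.07), Ctla4 (0.64 to 0.91) and Itgae (0.89 to 1.02) ended each time. Those of Gzmk ended without the CD4-negative library of sh1137 (-0.72) and without either library of sh4462 (-0.79 and -0.61). That of Zfp229 ended without the CD4-negative library of sh1137 (1.89), and that of mt-Nd4 there (1.1) and without the CD4-positive library of sh4462 (1.06). These omissions did not pair libraries by hairpin. With the hairpin block 3748 genes passed, 43.0% of them higher, while ERCC scaling moved all genes by 0.248 and left 19 calls, 89.5% of them higher. It ended the calls of Tjp1 (-1.78), Rgs16 (-1.80), Gzmd (-2.39), Eomes (-0.72) and Gzmk (-0.50). The DESeq2 Wald test left Rgs16 (-2.06) and Gzmd (-2.64) without an adjusted p, and Gzmd did not pass with limma voom (-2.51) or after thinning (-2.64).

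The next comparison asked whether CD4-positive cells differ from CD4-negative cells in the same way under both knock-downs. Cd4 itself differed most between the effects by p, rising 11.2-fold under Chaf1a and 47.2-fold under Dnmt1 knock-down, a difference of -2.08 ± 0.28 on the log2 scale (adjusted p = 0.0583). Khdc1a fell under Dnmt1 knock-down by more than under Chaf1a (difference 2.13 ± 0.29, adjusted p = 0.0583), as did Tjp1 (1.80 ± 0.33, adjusted p = 0.336). None of these differences passed in the main model. With the hairpin block 5 genes did, among them Cd4 (-2.08, adjusted p = 0.0207), Khdc1a (2.13, adjusted p = 0.0207) and Tjp1 (1.82, adjusted p = 0.0284) (the others were Gm6863 and Zfp781).

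The main edgeR test called 0 genes for this difference, with 459 at an unadjusted p under 0.05, while the DESeq2 Wald test called 8 and limma voom 0. It called 2 without the CD4-negative library of sh3118 and 3 without that of sh1137. Differences of Ifi206 (-1.04, adjusted p = 0.428), Fasl (-0.66), Cd8a (-0.51), Chaf1a (-0.11) and Dnmt1 (-0.02; the last 4 at adjusted p = 1) did not pass. That of Ifi206 did with the DESeq2 Wald test (-1.01, adjusted p = 0.0286) and without a filter on low counts (-0.99). The cytotoxic genes (median -0.21, adjusted p = 0.0130), p53 targets (0.20, adjusted p = 0.0130), mitochondrially encoded genes (-0.23, adjusted p = 0.0143), mitosis genes (-0.15, adjusted p = 0.0252) and interferon-stimulated genes (-0.24, adjusted p = 0.0371) passed the list test with no member called, over all genes or adjusted over the list alone (adjusted p = 0.884 with an estimated correlation for each). The effects of the knock-downs, which share no library, correlated across genes with Pearson 0.30 and Spearman 0.58 over 17002 genes, and with 0.89 and 0.87 over the 2000 genes of highest CPM, where genes are not independent replicates. Of the 2 calls higher under Chaf1a knock-down 1 is Cd4, which the sort fixed, so their overlap measures little. Of the 3 lower calls 2 were also lower under Dnmt1 (0.0242 expected among independent lists, Fisher's exact p = 0.000192). With the hairpin block 549 higher and 1338 lower genes were shared (80.0 and 244 expected), and 3 and 4 had opposite directions. Both effects followed transcript composition alike (Spearman -0.36 with GC content and 0.32 with length for each). Neither overlap nor correlation was computed after correcting for this, so how far that trend makes up the agreement was not tested.

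**Figure D2:**
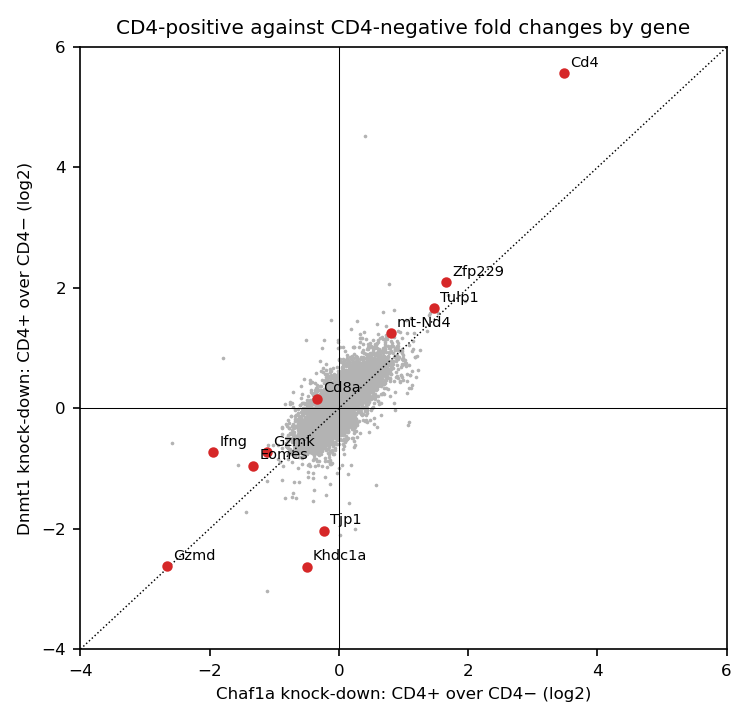
Log2 fold change of CD4-positive over CD4-negative cells under Chaf1a knock-down (x axis) and under Dnmt1 knock-down (y axis), with 1 grey point per gene of at least 5 CPM and named genes in red. The dotted line marks equal effects; Cd4 lies above it (3.48 and 5.56) and Khdc1a and Tjp1 lie below it, while Gzmd and Eomes are low on both axes.

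Chaf1a and Dnmt1 knock-down were compared directly, which asked how the states left by losing each factor differ. In CD4-negative cells, Chaf1a knock-down left more mRNA for Hspa1a, a heat shock protein, and for many interferon-stimulated and some imprinted genes, and Dnmt1 knock-down left far more Foxp3, the regulatory T cell factor (chromosome X, 7573644 to 7595245), and Klrg1, a receptor of terminal effector cells. Foxp3 stood at 605 ± 22.3 CPM (n = 2) under Dnmt1 and 16.4 ± 6.81 (n = 2) under Chaf1a knock-down, and Gzmk at 209 ± 2.20 (n = 2) and 18.3 ± 0.984 (n = 2). The interferon-induced Oasl2 stood at 33.7 ± 5.00 (n = 2) under Chaf1a and 1.64 ± 0.338 (n = 2) under Dnmt1 knock-down.

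In these cells 3134 genes passed, 1911 higher and 1223 lower under Chaf1a knock-down. Of 33 interferon-stimulated genes 13 were higher and 1 lower (16 and 3 adjusted over the list alone; median 0.48, camera adjusted p = 0.00211, adjusted p = 0.489 with an estimated correlation), with Ifit3 (4.53) and Oasl2 (4.36 ± 0.26, adjusted p = 4.09e-07). Ifit3 shares 61.8% of its sequence words with relatives. Of 20 imprinted genes 6 were higher and 2 lower (8 and 2 adjusted over the list alone; median 0.64, camera adjusted p = 0.00785, adjusted p = 0.489 with an estimated correlation), with the growth inhibitor Cdkn1c (4.44) and Peg3 (4.18). Of 16 stress genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.507 with an estimated correlation), led by Hspa1a (6.56 ± 0.30), which shares 70.1% of its words with other genes, mostly Hspa1b, and Atf3 (3.52). The summed level of the stress list was not higher (2150 and 2470 CPM with sh576 and sh3118, 2350 and 2440 with sh1137 and sh4462). MHC class II genes (5 of 8 higher, also adjusted over the list alone; median 1.33, camera adjusted p = 0.00785, adjusted p = 0.489 with an estimated correlation) included H2-Ab1 (2.13). Their summed level was low, at 21.5 to 80.3 CPM over the 9 libraries. The p53 targets (9 of 22 higher; 10 higher and 1 lower adjusted over the list alone; median 0.43, camera adjusted p = 0.0103, adjusted p = 0.539 with an estimated correlation) included the cell cycle inhibitor Cdkn1a (0.96). Il7r, the IL-7 receptor of naive and memory cells, was higher (2.08), and so was Setdb1, an H3K9 methyltransferase (1.54), whereas another, Ehmt2, was lower (-1.32). Vat1l was at least 200-fold and Slc5a5 at least 119-fold higher than in the Dnmt1 libraries, where both were at 0. Of 6 tested 2-cell embryo genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.553 with an estimated correlation), at levels that summed to 14.7 and 4.81 CPM in the Chaf1a libraries, 6.37 and 7.12 in the Dnmt1 ones and 9.88 in the control.

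Of 31 germline genes 8 were lower and 4 higher under Chaf1a knock-down (13 and 4 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.489 with an estimated correlation), with Gtsf1, a piRNA factor, at -5.08 ± 0.38. Foxp3 (-5.21 ± 0.30, adjusted p = 2.84e-07), of whose words 26.4% are shared with other transcripts, Klrg1 (-7.80 ± 0.41), the Fc receptor subunit Fcer1g (-3.82), Gzmk (-3.51 ± 0.14, adjusted p = 2.44e-08), Entpd1 (-2.43), Havcr2 (-2.08) and Tnfrsf4 (-2.03) were lower as well. Of 20 chemokine receptors and integrins 8 were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.51, camera adjusted p = 0.00593, adjusted p = 0.489 with an estimated correlation). Clvs1 (-6.49) and Zfp575 (-6.28), and Pira2, at least 153-fold, were lower. Pira2 shares 96.7%, Clvs1 35.3% and Zfp575 10.2% of their words with other genes. The targets moved as labelled, Chaf1a at -1.56 and Dnmt1 at 2.39, and Cd4 was 1.65-fold higher under Chaf1a knock-down (0.72 ± 0.23, adjusted p = 0.0481). That call of Cd4 ended with DESeq2 size factors (0.70), the DESeq2 Wald test (0.70), limma voom (0.72), correlated hairpins (0.71), a GC and length correction (0.66) and only the groups compared (0.71), and without any 1 of the libraries compared (0.71 without either Chaf1a library, 0.68 without the Dnmt1 library of sh1137, 0.74 without that of sh4462).

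In CD4-positive cells the same contrast gave 4025 genes, 2124 higher and 1901 lower. Foxp3 (-5.32 ± 0.30), Gzmk (-3.89), Fasl, a death ligand of cytotoxic cells (-2.55), Ctla4 (-1.79), Gtsf1 (-5.21) and Clvs1 (-6.91) were lower under Chaf1a knock-down, and Klrg1, at 0 in both Chaf1a libraries, was at least 162-fold lower. Hspa1a (5.97), Oasl2 (4.8), Cdkn1c (6.10), Peg3 (3.68), Il7r (2.30) and Cdkn1a (1.25) were higher, and H1fx, Mcpt8 and H2-Aa, at 0 in the Dnmt1 libraries, were at least 93.1-, 73.1- and 41.8-fold higher. Cd4 was lower in this contrast (-1.36 ± 0.16, adjusted p = 5.07e-05), as was Chaf1a (-1.67), and Dnmt1 was higher (2.37). Of 22 p53 targets 12 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.56, camera adjusted p = 0.000975, adjusted p = 0.470 with an estimated correlation). Of 28 mitosis genes 14 were lower (18 adjusted over the list alone; median -0.41, camera adjusted p = 0.000603, adjusted p = 0.606 with an estimated correlation), a median that stayed negative at -0.09 with ERCC scaling.

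Replication-dependent histones passed camera with the preset correlation in both sorts (medians -0.21 in CD4-negative and -0.31 in CD4-positive cells). Both medians were 0.02 with ERCC scaling. Scaling by ERCC reads moved all genes by 0.237 towards Chaf1a knock-down in CD4-negative cells, with 2182 calls, 87.0% of them higher against 61.0% in the main model, and by 0.309 in CD4-positive cells, with 2998 calls, 85.7% of them higher against 52.8%. Without either Dnmt1 library the CD4-negative count was 1883 (sh1137) or 1880 (sh4462), and the CD4-positive count was 2310 and 2612 without the Chaf1a libraries of sh576 and sh3118, and 2636 and 2683 without the Dnmt1 libraries of sh1137 and sh4462.

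**Figure D3:**
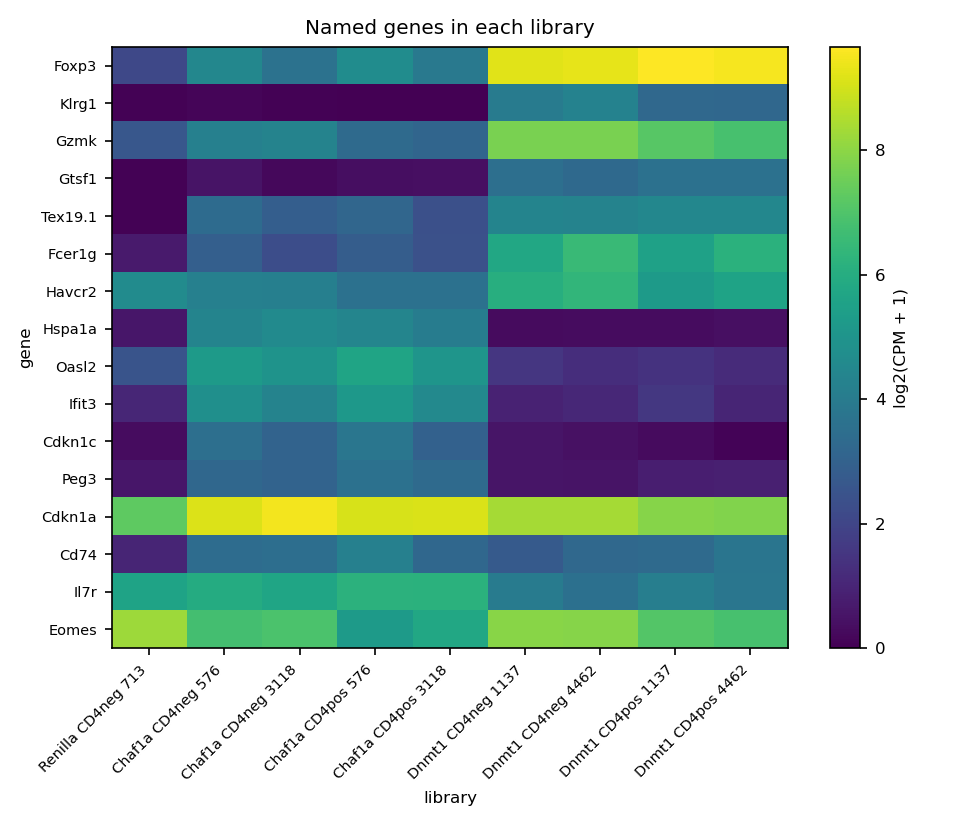
Expression of 16 named genes (rows) in each library (columns), as the colour-coded log2 of CPM plus 1. Foxp3, Klrg1 and Gzmk are highest in the 4 Dnmt1 libraries, and Hspa1a, Oasl2, Cdkn1c and Peg3 are highest in the 4 Chaf1a libraries.

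CD4-negative cells with Chaf1a knock-down had more mRNA than the single Renilla library for some genes of the interferon, p53, stress and MHC class II lists and for some germline and imprinted genes. Cdkn1a was at 152 CPM in that library and at 640 ± 112 (n = 2), and Oasl2 at 4.71 and 33.7 ± 5.00 (n = 2). Eomes was lower, at 304 and 115 ± 8.70 (n = 2), and Lrrc32, which presents latent TGF-beta, at 265 and 90.0 ± 1.86 (n = 2). Cd4 (0.65 ± 0.29, adjusted p = 0.170) did not pass in these CD4-negative cells.

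Of 2118 genes that passed, 1564 were higher and 554 lower (73.8% higher). Of 33 interferon-stimulated genes 14 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.72, camera adjusted p = 6.38e-06, adjusted p = 0.366 with an estimated correlation), with Ifit3 (4.45) and Oasl2 (2.84 ± 0.31, adjusted p = 9.34e-05). Of 22 p53 targets 12 rose (13 adjusted over the list alone; median 0.75, camera adjusted p = 9.66e-05, adjusted p = 0.366 with an estimated correlation), with Cdkn1a (2.07 ± 0.18, adjusted p = 1.76e-05), Plk2 (2.27) and Phlda3 (1.26). Of 16 stress genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.10, camera adjusted p = 0.00113, adjusted p = 0.366 with an estimated correlation), with Hspa1a (5.38) and Atf3 (3.06), while the summed level of the list was 2150 and 2470 CPM against 2190 in the control. Of 8 MHC class II genes 3 rose (7 adjusted over the list alone; median 2.10, camera adjusted p = 0.00224, adjusted p = 0.366 with an estimated correlation), among them Cd74 (3.30) and H2-Ab1 (2.51). Levels of this list were low, with a sum of 21.5 to 80.3 CPM over the 9 libraries and a median gene at 5.28 CPM at most. Imprinted genes (6 of 20 higher and 1 lower; 7 and 2 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.366 with an estimated correlation) included Grb10 (5.45), Cdkn1c (5.22) and Peg3 (3.93). Germline genes (7 of 31 higher; 8 adjusted over the list alone; camera adjusted p = 0.0142, adjusted p = 0.397 with an estimated correlation) included Tex19.1 and Tex19.2. These had 1 and 2 counts in the control, for ratios of 235 (95% counting interval 42.0 to 9310) and 59.0 (16.2 to 491). NK and innate-like receptors rose in 4 of 8 cases (4 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.456 with an estimated correlation), with Klrb1a at least 37.4-fold higher. Cholesterol synthesis genes fell in 7 of 20 cases (7 adjusted over the list alone; median -0.35, camera adjusted p = 0.00459, adjusted p = 0.702 with an estimated correlation), with Sc5d (-0.84) and Insig1 (-0.81). Epb41l4b and Vat1l, at 0 in the control, were at least 217- and 101-fold higher. Setdb1 rose (1.26) and Ehmt2 fell (-0.82), Zbtb7b (1.07), Foxp3 (2.32) and Gzmk (1.82) rose, and Eomes (-1.41), Lrrc32 (-1.56) and Chaf1a (-1.26 ± 0.18, adjusted p = 0.000644) fell, while Dnmt1 (0.37, adjusted p = 0.225) did not pass.

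ERCC scaling moved all genes by -0.118 here and left 884 calls, 87.7% of them higher, without Zbtb7b (0.95). A correction for GC content and length gave 2426 calls, 58.0% of them higher, and fold changes correlated with GC content (Spearman 0.28 across 10144 genes).

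CD4-negative cells with Dnmt1 knock-down had more mRNA than the single Renilla library for Foxp3 and for some genes of germ cells, of NK cells and of helper T cells, and less for some genes of naive and memory T cells. Foxp3 was at 3.28 CPM in that library and at 605 ± 22.3 (n = 2) under knock-down, and Gzmk at 5.18 and 209 ± 2.20 (n = 2). Il7r was lower, at 47.3 and 13.1 ± 3.04 (n = 2). Cd4 did not pass in these cells, which had been sorted as CD4-negative (-0.08 ± 0.30, adjusted p = 0.954).

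In this comparison 833 genes passed, 678 higher and 155 lower (81.4% higher). Of 31 germline genes 6 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.05e-07, adjusted p = 0.195 with an estimated correlation). Tex19.1 and Gtsf1 had 1 count in the control, for ratios of 569 (95% counting interval 102 to 22500) and 286 (51.1 to 11300), Tex19.2 had 2, for a ratio of 138 (38.0 to 1140), and Tuba3b was at 0 there and at least 49.3-fold higher. Of 17 CD4 helper genes 5 rose (5 adjusted over the list alone; median 0.98, camera adjusted p = 0.000814, adjusted p = 0.195 with an estimated correlation), with Foxp3 (7.52 ± 0.47, adjusted p = 3.77e-06), the co-stimulatory receptor Tnfrsf4 (1.87) and Zbtb7b (1.55 ± 0.18, adjusted p = 0.000335). Of 20 chemokine receptors and integrins 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.000786, adjusted p = 0.354 with an estimated correlation), with Itgae (2.01). Of 8 NK and innate-like receptors 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00578, adjusted p = 0.475 with an estimated correlation), with the signalling adaptors Fcer1g (6.90) and Tyrobp (3.15). Of 17 naive and memory genes 6 fell (12 adjusted over the list alone; median -0.67, camera adjusted p = 4.55e-05, adjusted p = 0.475 with an estimated correlation), with Il7r (-1.86 ± 0.20, adjusted p = 0.000142) and the transcription factor Tcf7 (-1.43). Of 22 activation and inhibitory receptors 8 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.17, -0.19 with ERCC scaling; camera adjusted p = 0.0321, adjusted p = 0.475 with an estimated correlation), with Entpd1 (2.05) and Havcr2 (1.57). The p53 targets passed camera with the preset correlation here too, and not with an estimated one (median 0.23, -0.11 with ERCC scaling). Klrg1 (chromosome 6, 122270596 to 122282882) had 1 count in the control, for a ratio of 495 (88.7 to 19600). Gzmk (5.33 ± 0.22, adjusted p = 1.06e-07), Gzma (1.46), Slc16a3 (1.5) and Tmprss6, at least 45.3-fold, were higher. Il10 (-2.41), Oasl2 (-1.52), the methylcytosine dioxygenase Tet1 (-1.74) and Dnmt1 itself (-2.03 ± 0.17, adjusted p = 2.39e-05) were lower, and Chaf1a (0.30, adjusted p = 0.463; -0.06 with ERCC scaling) did not pass.

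With only these 3 libraries in the edgeR model, 0 genes passed, with 2435 at an unadjusted p under 0.05. With all 9 libraries the DESeq2 Wald test called 1061 genes and limma voom 690. The edgeR count was 523 without the library of sh4462, where the call of Oasl2 (-1.30) ended. Oasl2 (-1.53) and Tyrobp (3.01) did not pass with limma voom. ERCC scaling moved all genes by -0.356 and left 322 calls, 58.4% of them higher, without Tyrobp (2.83), Havcr2 (1.23) and Slc16a3 (1.15), and of genes with a mean of at least 5 CPM 71.1% of the calls were higher.

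The comparisons with the control had genes in common. Foxp3, Gzmk, Zbtb7b, Tex19.1 and Tex19.2 were higher under both knock-downs, and 317 genes in all were (62.4 from n1 × n2 / N), while 50 were lower under both (5.05). Those products hold for independent comparisons, and these share the Renilla library, so they do not measure the overlap due to the knock-downs. Oasl2 was among the 15 genes higher under Chaf1a and lower under Dnmt1 knock-down, and 11 genes had the reverse pattern. Fold changes correlated with Pearson 0.52 across 17002 genes, less than in simulated unchanged groups that share the control (0.72), and their covariance was 0.913 against 0.357 simulated. Part of the excess covariance (0.556) may come from the shared control, which is a single library and cannot be split.

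**Figure D4:**
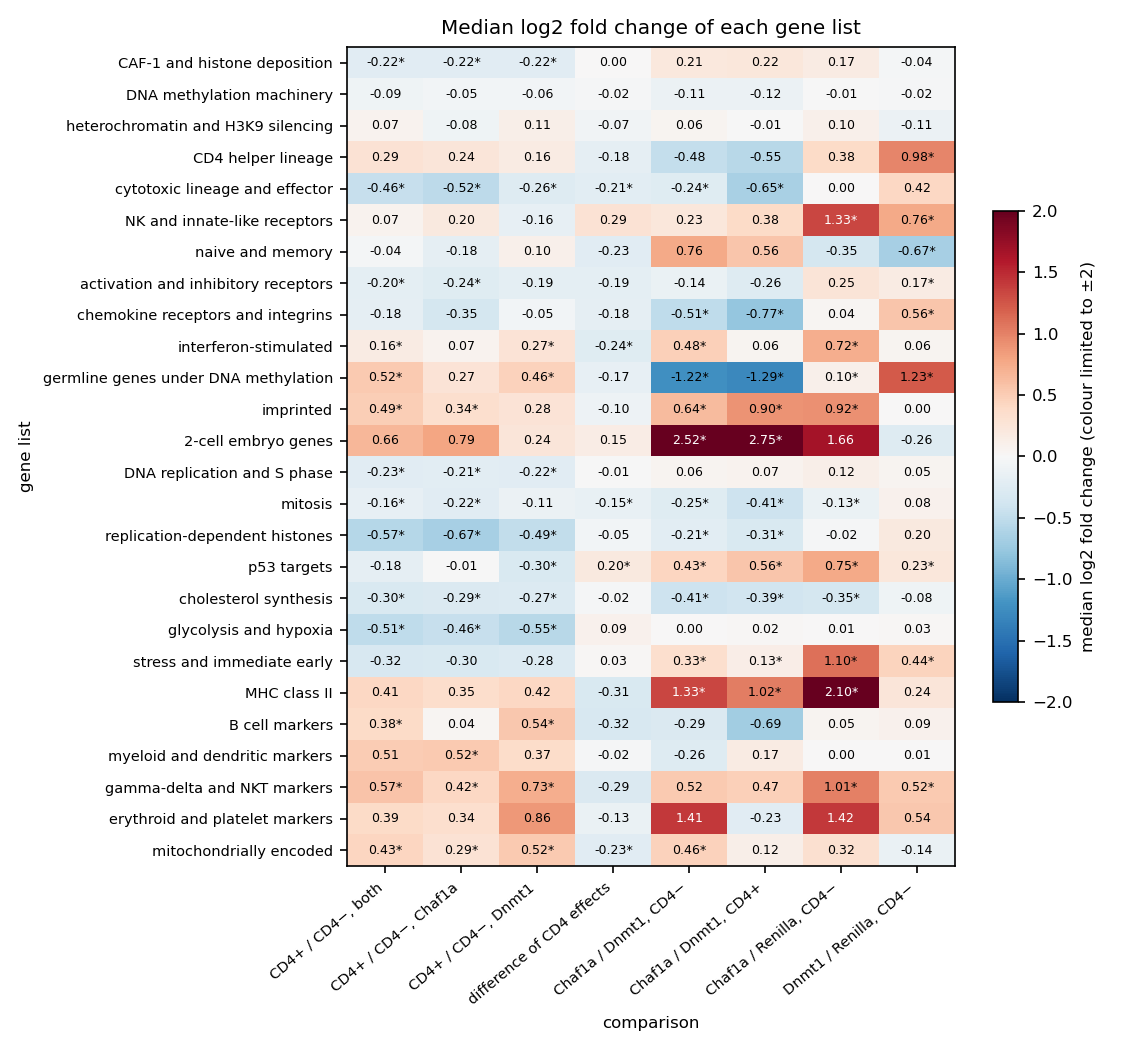
Median log2 fold change of each of 26 gene lists (rows) in each of 8 comparisons (columns), with an asterisk where camera with a preset correlation of 0.01 passed at an adjusted p of 0.05 and genes at 0 on one side held at the bound of 3 counts. Cytotoxic, histone and glycolysis genes are low in the CD4-positive columns, and interferon-stimulated genes, p53 targets and MHC class II genes are high under Chaf1a knock-down; none of the asterisks holds with an estimated correlation, with ERCC scaling, starred medians change sign for replication and CAF-1 genes in the 3 CD4-positive columns, mitosis and activation genes in the first 2, cholesterol genes under Chaf1a, histones in Chaf1a against Dnmt1, and activation genes and p53 targets in Dnmt1 against Renilla.

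**Figure D5:**
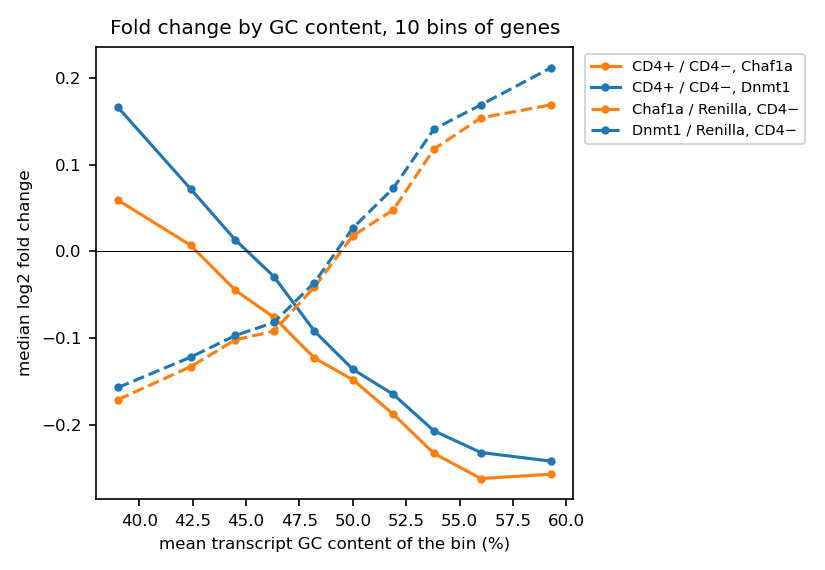
Median log2 fold change of genes in 10 bins of transcript GC content (x axis, percent), for CD4-positive over CD4-negative cells (solid lines) and for each knock-down over the control (dashed lines). The solid lines fall and the dashed lines rise with GC content.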

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

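The tests of GC content and length, of depth, of the GC trend against the control, and of all genes higher than the control were chosen after the result was seen, and the other tests in this part before. No group had the 4 libraries that a test for a single deviating library needs. The results listed first had unlike estimates of the effect of CD4 sorting in the knock-downs (difference as Chaf1a minus Dnmt1). None of these differences passed in the main model.

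Cd4 rose less in CD4-positive over CD4-negative cells under Chaf1a than under Dnmt1 knock-down (difference -2.08, adjusted p = 0.0583; 0.0207 with the hairpin block), and Cd4 is also the marker of the sort. Cd8a fell with both Chaf1a hairpins (-0.25 and -0.43) and rose with both Dnmt1 hairpins (0.12 and 0.20), a difference of -0.51 (adjusted p = 1). Ifi206 went -0.77 and -0.29 against 0.50 and 0.48 (difference -1.04, adjusted p = 0.428, and 0.0286 with the DESeq2 Wald test). Tex19.1 went -0.20 and -0.61 against 0.15 and 0.13 (difference -0.51, adjusted p = 1). Oasl2 went 0.40 and 0.06 against -0.19 and -0.15 (difference 0.44, adjusted p = 1). Il10 went 0.25 and 0.01 against -1.34 and -0.42 (difference 1.23, adjusted p = 1).

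The first pattern weighed was the breadth of the difference between CD4-positive and CD4-negative cells, 3529 genes. Depth as its whole source was argued against, since 3455 genes passed after thinning all libraries to equal depth. GC content and length as its whole source were argued against, since 5873 genes passed with the hairpin block and a correction for both, against 6282 with the block alone. Of all 34 splits of the 8 knock-down libraries, only 1, the real one, gave as many (4025 in a model with the knock-down as a term). The highest other gave 2394 and parted 2 of the 4 hairpin pairs. Splits that keep the libraries of a hairpin together are no fair measure of chance for a difference within hairpins. The 8 splits that part all 4 pairs (highest other 1) are too few for a share under 0.05, so chance was not excluded. A difference that goes with sorting for CD4, such as growth rate or cell size, was not tested and stays open, as no control was sorted CD4-positive.

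The second pattern was that knock-down libraries differed from the Renilla library mostly by higher expression. The CD4-positive libraries were used to ask whether the single Renilla library was the whole source. There 66.6% of the 1564 genes higher under Chaf1a were called higher than under Dnmt1 (12.5% of all genes). Of the 678 genes higher under Dnmt1, 56.6% were called higher than under Chaf1a (11.2% of all genes). Most genes of both sets were higher under 1 knock-down alone, which picked them for a difference between the knock-downs. Their own shares (77.1% of 1247 and 87.5% of 361) were not counted as evidence. Because the shares of the whole sets rest largely on those genes, they do not decide where the lean comes from. They show that many of these genes differed between the knock-downs in libraries other than the Renilla library. For the 317 higher under both, of which 25.2% were called higher there under Chaf1a and 21.5% under Dnmt1, a loss of silencing and a feature of the Renilla library cannot be told apart, because both comparisons use the same library. GC content and length as the whole source were argued against by the share of higher calls after correction, 58% under Chaf1a and 72.2% under Dnmt1, down from 73.8% and 81.4%, so part of the lean may follow transcript composition.

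The third pattern was a set of 424 genes at least 8-fold higher under Chaf1a knock-down than in the Renilla library. The single Renilla library was argued against as the source of the set as a whole by a median fold of 9.21 over Dnmt1 knock-down in the CD4-positive libraries, where 341 of the 424 were called higher, while of the other 83, 40 were called higher under Dnmt1 than in the Renilla library. Cells of another type, which the sort on CD8 would remove, stay open: epithelial and fibroblast markers had a median of 0.329 CPM in the Chaf1a libraries, against 3.1 CPM for the set, just above the bound set before the test. Erythroid and platelet markers, 2 of 5 called higher but not past the threshold as a list (median 1.42, adjusted p = 0.0722; 0.0394 with fry), summed to 13.1 and 6.65 CPM in the Chaf1a CD4-negative libraries, 3.75 and 4.53 under Dnmt1 and 1.93 in the Renilla library. Among the 13 epithelial and fibroblast markers Krt8 and Dcn were at 0.0658 CPM or less in these 4 libraries, and Cdh1 at 37.1 to 48.9 CPM (40.8 to 57.1 under Dnmt1, 12.3 in the Renilla library), so lost silencing of T cell genes may account for the set only as a hypothesis.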

How the results depend on the processing

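The alternatives with ERCC scaling, GC and length correction, or thinning to equal depth, and the overlap with the hairpin block, were chosen after seeing the data, and all others before. Over 255 values for named genes and lists, the alternatives left direction and side of the threshold as they were in 2497 cases, ended 271 calls, added 33 and turned the direction in 15, all single genes. Lists were not counted there under ERCC scaling, which turned the medians given with the list tests. Of the counts and correlations of whole comparisons, 92 stayed (counts within 1.5 times the reported one) and 66 moved. Where no reason is given, the cause was not tested.

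With the hairpin block, 6282 genes passed for CD4-positive against CD4-negative cells over both knock-downs, 2786 for Chaf1a, 3748 for Dnmt1 and 5 for the difference between these effects. With the block and the GC and length correction these were 5873, 2576, 3769 and 6. Shared calls in the CD4 effect, 2 higher and 2 lower, became 549 and 1338 with the block and 418 and 1116 at an adjusted p under 0.20, where more genes enter by construction.

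ERCC scaling gave 1740, 8 and 19 genes for the CD4 effect over both, in Chaf1a and in Dnmt1, and 884 and 322 for Chaf1a and Dnmt1 against the control. The DESeq2 Wald test gave 691 for Chaf1a, 1718 for Dnmt1 and 8 for the difference between the effects. Without a filter on low counts these 3 were 971, 2289 and 34, and Dnmt1 against the control gave 1323. With a mean of at least 5 CPM, Chaf1a gave 2 and Dnmt1 588, and the correlation of the control comparisons was 0.50. With only the groups compared, Chaf1a gave 43, Dnmt1 1249 and Dnmt1 against the control 0, where 3 libraries leave fewer degrees of freedom. Thinning gave 8 for Chaf1a. The correlation of the CD4 effects was 0.89 in the 2000 genes of highest CPM.

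Of the list tests, 0 passed with an estimated correlation in each of the 8 comparisons. With fry, 8 passed over both knock-downs, 1 in Chaf1a, 0 in Dnmt1 and 0 for the difference, against 14, 12, 12 and 5 with camera. ERCC scaling turned medians of lists that had passed: over both knock-downs replication (-0.23 to 0.06), mitosis (-0.16 to 0.13), CAF-1 (-0.22 to 0.07) and activation genes (-0.20 to 0.08), in Chaf1a the same 4 (to 0.12, 0.11, 0.11 and 0.09) and cholesterol genes (-0.29 to 0.04), and in Dnmt1 replication and CAF-1 genes (to 0.01 and 0.02). It turned histones in Chaf1a against Dnmt1 (-0.21 and -0.31 to 0.02 in CD4-negative and CD4-positive cells), and activation genes (0.17 to -0.19) and p53 targets (0.23 to -0.11) in Dnmt1 against the control.

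Leaving out 1 library at a time gave 334 to 5804 genes for the CD4 effect over both knock-downs, 1 to 2619 in Chaf1a, 6 to 31 in Dnmt1, 0 to 3 for the difference, 1880 to 2969 for Chaf1a against Dnmt1 in CD4-negative cells, 2310 to 2683 in CD4-positive cells, 1848 to 2685 for Chaf1a and 523 to 595 for Dnmt1 against the control. A group left with 1 library was assumed to vary like the other groups, and these fits did not pair libraries by hairpin.

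Among single genes, over both knock-downs ERCC scaling turned Cd8a to 0.20, Cd8b1 to 0.12 and Chaf1b to 0.06, and the filter at 5 CPM turned Cd8a to 0.01. Against the control, ERCC scaling turned Chaf1a under Dnmt1 knock-down to -0.06. For the difference between the effects, Chaf1a (-0.27 to 0.10 over single libraries left out) turned to 0.10 without the CD4-negative library of sh576, 0.03 without the CD4-positive library of sh1137 and 0.03 without the CD4-negative library of sh4462. Dnmt1 turned to 0.01 with DESeq2 size factors and with the DESeq2 Wald test, 0.03 without a filter and 0.05 with ERCC scaling. It ranged from -0.24 to 0.22 over single libraries left out, and turned to 0.02 without the CD4-positive library of sh576, 0.16 without the CD4-negative library of sh3118 and 0.22 without the CD4-negative library of sh4462.

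Depth limited the lowest levels: a gene at 1 CPM rested on 24 counts in the shallowest library, an error of 20.4%.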

Other observations

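The GC and length correction and the comparison of hairpins in this part were chosen after the result was seen, and the other tests before. Libraries of hairpins against the same gene differed, and the labels do not show whether hairpin or culture separates them. With the CD4 sort held fixed, 193 genes differed between Chaf1a hairpins sh576 and sh3118 (110 higher and 83 lower with sh576, 49 of them at least 2-fold), and 40 differed between Dnmt1 hairpins sh1137 and sh4462 (22 higher and 18 lower with sh1137, 11 at least 2-fold). At an unadjusted p under 0.05 in edgeR there were 3077 and 2368 genes. The CD4-negative library of hairpin sh576 had 14.7 CPM in summed 2-cell embryo genes, and that of sh3118 had 4.81.

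ERCC reads numbered 3469 and 3914 in the Chaf1a CD4-negative libraries (sh576 and sh3118), 2873 and 3024 in the CD4-positive ones, 4878 and 4178 in the Dnmt1 CD4-negative ones (sh1137 and sh4462), 3738 and 2929 in the CD4-positive ones, and 3537 in the Renilla library.

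One hypothesis was that CD4-positive cells carry more of the knock-down effect than CD4-negative cells of the same hairpin. To keep libraries apart, genes higher than Renilla in the CD4-negative library of one hairpin were followed in the CD4 effect of the other hairpin. Their median CD4 effect exceeded that of other genes by 0.15 (genes from sh576, effect of sh3118), 0.23 (sh3118, sh576), 0.127 (sh1137, sh4462) and 0.232 (sh4462, sh1137), and by 0.199, 0.253, 0.208 and 0.294 after the GC and length correction. The smallest of these, 0.127, was in the direction the hypothesis needs, so a stronger effect in CD4-positive cells may be part of the difference. In the same order and before correction, the raised genes had median CD4 effects of 0.01, 0.14, 0.05 and 0.18. Other genes had -0.14, -0.09, -0.07 and -0.05. Part of each gap thus came from lower medians of other genes, and the sets were not matched by expression level. Across all genes, which are not independent replicates, the correlations were weak (Pearson 0.10, 0.05, -0.17 and 0.09). The largest in size, -0.17, ran against the hypothesis, for the pair that gave 0.127. The hypothesis thus rests on the genes raised and not on the whole profile.

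Another hypothesis was that lost silencing favours the X chromosome, which carries Foxp3. Of genes at least 8-fold higher than in the Renilla library, with a known position, 15 of 419 were X-linked under Chaf1a knock-down (odds ratio 0.903, 95% interval 0.498 to 1.52, Fisher's exact test, adjusted p = 0.80) and 9 of 117 under Dnmt1 knock-down (odds ratio 2.05, 0.907 to 4.05, adjusted p = 0.101). Neither passed, and the intervals leave an enrichment open.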
